A study of Homo sapiens with 12 samples.

How the data were processed

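RNA was measured in TF-1 cells, a human erythroleukaemia line that depends on the cytokine GM-CSF. The cells had been transduced with a retroviral vector that was empty or carried the K89E mutant of GNB1, a G protein beta subunit. Per the labels, total RNA came from biological triplicates, and biotin-labelled cRNA was made by the Affymetrix protocol. The 12 arrays fall into 4 groups of 3, in which each line was sampled with GM-CSF kept and 12 hours after its withdrawal.

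The deposited values are intensities on a linear scale, already normalized by the authors. RMA is the method named in the submitters' processing notes, and its version, the array type, the probe set definitions and the genome build are not given in the sources used here. The deposited table has 21996 rows, each carrying 1 Ensembl gene ID, so no choice between probe sets of a gene was needed. The intensities ran from 9.31 to 17477 and the array medians from 172.6 to 179.9. No column of the table was left without a sample. The number of arrays limits the precision. No batch or date of hybridisation is given in the sources used here, so an order of processing that follows the groups cannot be told apart from them.

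Intensities were converted to log2 without a pseudocount. The main test was limma 3.58.1 in R 4.3.3, fitted to all 12 arrays with 1 mean per group and a trend of the prior variance with level. Tests were 2-sided. The p-values were adjusted with the Benjamini-Hochberg method over all 21996 genes, separately for each comparison, and a gene was called at an adjusted p under 0.05. The 5 comparisons were K89E against empty vector without and with GM-CSF, withdrawal against GM-CSF in each line, and the difference between both withdrawal responses. The design, the alternatives and the rule for named genes were fixed before the data were examined. The alternatives were a prior variance without a trend or made robust, leaving out the dimmest 33.3% of the genes, quantile normalization, centring on array medians, array weights, the replicate number as a block, fits on 2 groups, a change of at least 2-fold, a pseudocount of 16 and leaving out each array.

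The similarity of responses was measured by correlations and slopes across genes. Because noise in the changes lowers both, corrected values were also computed after the noise variance of the group means was subtracted. These corrected values, a fit with 1 weight per group, and the pseudocount and scaling alternatives for correlations and slopes were added after the data were seen. The error of a slope or correlation is a jackknife SE over the 12 arrays.

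The procedure was tested on simulated data for all 21996 genes. For K89E against empty vector without GM-CSF, the test recovered 41.8% of the genes changed 1.2-fold, 97.0% of those changed 1.5-fold and 100% of those changed 2-fold. For the difference between responses these shares were 17.9%, 74.6% and 93.9%. Each simulation changed 67, 67 and 66 genes by these folds, and 15 and 5 unchanged genes were called in the 2 comparisons. Its noise was independent between genes and, for a gene, equal in all groups. Within groups, real withdrawn arrays spread 1.26 times as much as GM-CSF arrays, so the shares in the real data can differ. For K89E against empty vector without GM-CSF, 2756 real genes were called, far more than were changed here. This also alters the adjusted threshold. Simulated response slopes of 0.7, 0.9 and 1 were recovered as 0.698, 0.900 and 1.01 after correction. Their signal was the measured empty vector change, and their noise was independent between genes. These recoveries therefore do not show how precise the corrected slope of the real data is.

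The files do not pair the Ensembl IDs with gene symbols. The reference table used here, made from the GRCh38.p14 assembly, gives an Ensembl ID in 0 of its 59792 rows, so no ID could be matched. Gene names are therefore not given, and the level of GNB1 and the 33 gene lists fixed in advance were not analysed here. The rule for named genes ranked called genes by size of change where the 3 arrays of one group all lay beyond those of the other. In place of the planned 12 per direction, only the first ID in each direction was named, from K89E against empty vector without GM-CSF and from withdrawal in empty vector cells. The planned check of RNA quality needs control probe sets and was not made, since the table used here holds 0 of them.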

Results

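The series asked how gene expression in TF-1 cells differed between cells carrying GNB1 K89E and cells carrying an empty vector, with GM-CSF present or withdrawn. Levels of 21996 genes were measured on 12 arrays, 3 per group. Array medians lay between 172.6 and 174.3 in the cells kept in GM-CSF and between 174.3 and 179.9 after withdrawal. Across all genes, log2 levels of arrays of the same group correlated at 0.996 to 0.999, and those of different groups at 0.993 to 0.997. Genes are identified by Ensembl ID because the files do not pair the IDs with symbols.

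The 4 groups separated on the first 2 principal components. The first held 31.7% of the variance and parted withdrawn from GM-CSF arrays. Its mean score was 12.96 ± 1.33 (SD, n = 3) in withdrawn and -10.6 ± 1.37 (SD, n = 3) in GM-CSF arrays of empty vector cells, against 9.27 ± 1.92 (SD, n = 3) and -11.7 ± 1.06 (SD, n = 3) in K89E cells. The second held 25.6% and parted the lines, with K89E means of 12.0 ± 2.34 (SD, n = 3) and 7.89 ± 1.16 (SD, n = 3) and empty vector means of -9.88 ± 1.03 (SD, n = 3) and -10.0 ± 0.390 (SD, n = 3), withdrawn first in each line.

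**Figure D1:**
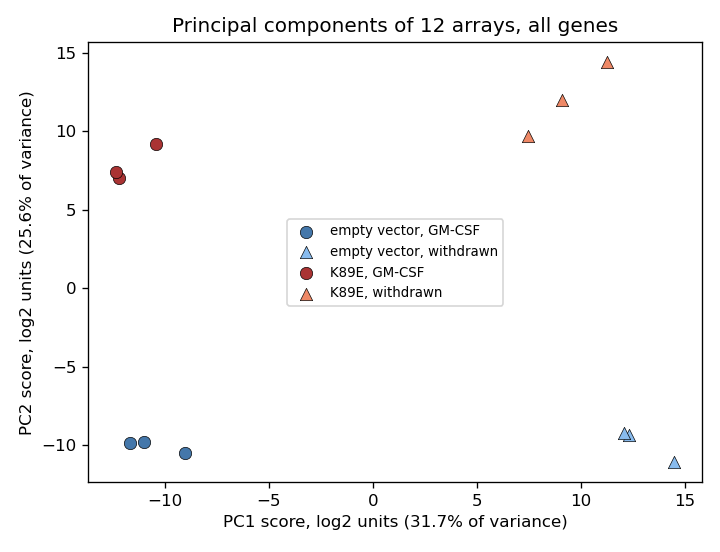
Scores of the 12 arrays on the first principal component (x axis, log2 units, 31.7% of the variance) and the second (y axis, log2 units, 25.6%), with 1 point per array. Withdrawn arrays (triangles) lie to the right of GM-CSF arrays (circles), and K89E arrays (red shades) lie above empty vector arrays (blue shades).

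In the main fit, withdrawal of GM-CSF from empty vector cells gave the largest number of calls of the 5 comparisons. Expression rose for 1920 genes and fell for 2572, together 20.4% of those measured. Without empty vector GM-CSF replicate 2, fewer genes were called here (3303) than for withdrawal in K89E cells (3627). The same order held without empty vector GM-CSF replicate 3 or empty vector withdrawn replicate 1. Most changes in the main fit were small, with a median absolute log2 change of 0.23 among called genes. Changes of at least 2-fold were seen in 14 genes that rose and 14 that fell, and changes of at least 1.5-fold in 123 and 71. The largest rise was that of ENSG00000120738, from a log2 level of 8.60 ± 0.02 (SD, n = 3) with GM-CSF to 10.67 ± 0.07 (SD, n = 3) without it. Its log2 change was 2.08 (SE 0.04, limma adjusted p = 4.4e-13), or 4.22-fold. The largest fall was that of ENSG00000167286, from 10.07 ± 0.13 (SD, n = 3) to 8.62 ± 0.10 (SD, n = 3), a log2 change of -1.44 (SE 0.07, limma adjusted p = 1.4e-08). The arrays of both groups did not overlap for 4452 of the called genes and for 35.7% of all genes, where chance gives 10%. Centring the arrays on their medians moved the split of calls to 1378 higher and 3211 lower. Quantile normalization moved it the other way, to 2028 higher and 2294 lower.

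In K89E cells withdrawal raised 1603 genes and lowered 2334, together 17.9% of those measured. At least 2-fold changes numbered 9 and 5, and at least 1.5-fold changes 83 and 38. ENSG00000120738 rose here too, from 8.82 ± 0.05 (SD, n = 3) to 10.55 ± 0.02 (SD, n = 3), a log2 change of 1.74 (SE 0.04, limma adjusted p = 5.3e-12). ENSG00000167286 fell from 10.64 ± 0.09 (SD, n = 3) to 9.86 ± 0.08 (SD, n = 3), a log2 change of -0.78 (SE 0.07, limma adjusted p = 4.3e-06). Both IDs had been picked for their changes in empty vector cells. The largest fall of a called gene in K89E cells was that of another gene. Its log2 change was -1.49, where the largest fall in empty vector cells was -1.44. The median absolute log2 change of called genes was 0.23. Arrays did not overlap for 3849 of them and for 31.8% of all genes, where chance gives 10%. The split of calls was 1736 higher and 1972 lower after quantile normalization, and 1308 and 2530 after centring on array medians.

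Most genes called in one line were also called in the other, in the same direction. The 2 responses share no array. Rises in both lines were called for 1115 genes, where independent lists would share 140, and falls in both for 1817, where they would share 273. Bright genes were called more often in both lines, so lists independent at a given level would share more. That number was not computed. Only 6 genes were called in opposite directions. Of the genes that rose in empty vector cells, 96.8% had a positive change in K89E cells, and of those that fell, 97.1% had a negative one. Across all genes, which are not independent replicates, the 2 responses correlated at r = 0.728 (jackknife SE 0.0463). With the noise variance removed, this correlation was 0.999 (jackknife SE 0.108).

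The slope of the K89E response on the empty vector response was 0.749 (jackknife SE 0.0694) over genes called in empty vector cells. The reverse slope was 0.939 (jackknife SE 0.121) over genes called in K89E cells. With the noise variance removed, the slope over all genes was 0.887 (jackknife SE 0.124) and the reverse slope 1.13 (jackknife SE 0.187). The corrected slope lay within 1 SE of equal responses.

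The difference between the withdrawal responses, tested gene by gene, was called for 15 genes. In 13 of them the difference, K89E response minus empty vector response, was positive, and all 13 fell on withdrawal in empty vector cells. The other 2 had a negative difference and rose in empty vector cells. All 15 changed less in K89E cells in absolute terms. The change there had the opposite sign in 4 of them, and 12 of the 15 were called for withdrawal in K89E cells. The median log2 change of the 13 was -0.59 in empty vector and -0.22 in K89E cells. The called gene with the largest positive difference was ENSG00000167286 (log2 difference 0.66, SE 0.10, limma adjusted p = 0.027), and that with the largest negative difference was ENSG00000120738 (log2 difference -0.34, SE 0.06, limma adjusted p = 0.045). With a prior variance without a trend, 5 genes were called and neither of these was, at limma adjusted p = 0.17 and 0.21. With 1 array left out, the adjusted p of ENSG00000120738 was 0.063 to 0.16 and its call was lost in all 12 fits, and that of ENSG00000167286 was 0.016 to 0.13. No called difference reached 2-fold, and 1234 genes had an unadjusted p under 0.05, where chance gives 1100. With 1 array left out, each of the 15 differences kept 85.6% to 113% of its size, while the count, taken with fewer arrays, changed. It was 0 without K89E withdrawn replicate 1 or 3 or empty vector GM-CSF replicate 2 or 3, 1 without K89E GM-CSF replicate 2, 5 or 6 without any 1 empty vector withdrawn array, 8 without K89E GM-CSF replicate 3, 9 without empty vector GM-CSF replicate 1 and 13 without either other array. Centring on array medians gave 12 positive and 0 negative differences.

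**Figure D2:**
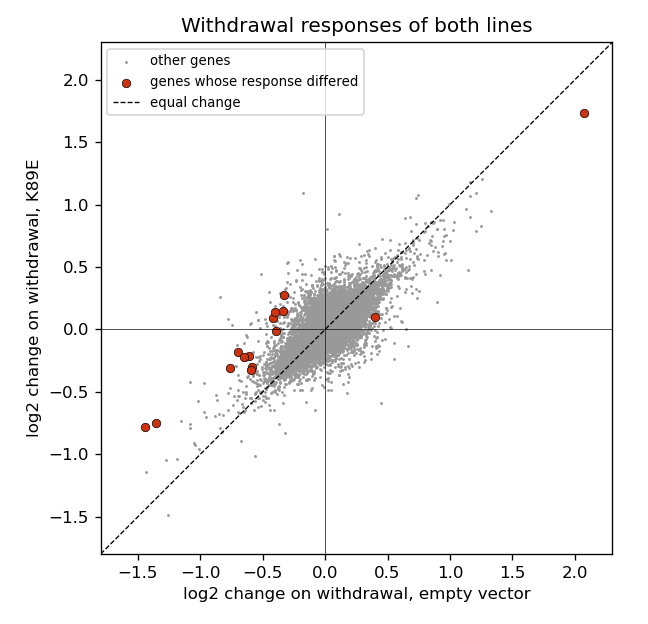
Log2 change on GM-CSF withdrawal in empty vector cells (x axis) and in K89E cells (y axis), with 1 point per gene. Red points are the 15 genes whose response differed at an adjusted p under 0.05; they lie nearer to no change in K89E cells than the dashed line of equal change.

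After withdrawal, K89E cells differed from empty vector cells in 12.5% of the genes, with 1434 higher and 1322 lower in K89E cells. At least 2-fold differences numbered 33 higher and 6 lower, and at least 1.5-fold differences 163 and 39. ENSG00000165929 had the largest rise, from 7.63 ± 0.16 (SD, n = 3) in empty vector to 9.64 ± 0.15 (SD, n = 3) in K89E cells, a log2 difference of 2.01 (SE 0.10, limma adjusted p = 2.9e-08) or 4.02-fold. ENSG00000166265 was lowest relative to empty vector cells, at 7.08 ± 0.27 (SD, n = 3) against 8.67 ± 0.14 (SD, n = 3), a log2 difference of -1.59 (SE 0.14, limma adjusted p = 3.7e-06). ENSG00000167286, the gene that fell furthest on withdrawal in empty vector cells, was higher in K89E cells by 1.23 (SE 0.07, limma adjusted p = 8.4e-08) on the log2 scale. With GM-CSF kept it was already higher in K89E cells, by 0.57 (SE 0.07, limma adjusted p = 1.1e-04). Of all genes, 25.4% had arrays that did not overlap, where chance gives 10%. Centring on array medians moved the split to 1488 higher and 910 lower. The fit on these 2 groups alone called 1756 genes, of which 742 were lower. Without empty vector withdrawn replicate 2, 868 genes were lower.

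With GM-CSF kept, 1147 genes were higher and 966 lower in K89E cells, together 9.61% of those measured. In the main fit this was fewer than after withdrawal. The order reversed in fits on 2 groups (2348 with GM-CSF, 1756 after withdrawal) and with array weights (3226 and 2767). It also reversed with 1 weight per group (2905 and 1999) and without K89E withdrawn replicate 2 (2225 and 2175). The other settings kept the main order. At least 2-fold differences numbered 22 higher and 1 lower, and at least 1.5-fold differences 102 and 30. ENSG00000165929 was higher in K89E cells here as well, at 9.74 ± 0.16 (SD, n = 3) against 8.28 ± 0.10 (SD, n = 3), a log2 difference of 1.46 (SE 0.10, limma adjusted p = 7.6e-07). ENSG00000166265 was lower, at 7.04 ± 0.26 (SD, n = 3) against 8.61 ± 0.12 (SD, n = 3), a log2 difference of -1.56 (SE 0.14, limma adjusted p = 6.9e-06). ENSG00000120738 was higher in K89E cells with GM-CSF kept, by 0.22 (SE 0.04, limma adjusted p = 0.0026) on the log2 scale. After withdrawal its difference was not called (-0.12, SE 0.04, limma adjusted p = 0.062). Arrays did not overlap for 28.7% of all genes, where chance gives 10%. The count of calls fell from 2113 to 1307 without empty vector GM-CSF replicate 2, to 1403 without empty vector GM-CSF replicate 3 and to 1398 without K89E GM-CSF replicate 2, and it rose to 3226 with array weights. Genes lower in K89E cells numbered 550 to 641 without any 1 of these 3 arrays, of empty vector GM-CSF replicate 1 or of K89E GM-CSF replicate 3, and without empty vector GM-CSF replicate 2 the genes higher numbered 757.

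The K89E effects with and without GM-CSF, which share no array, overlapped. Higher levels in K89E cells were called under both conditions for 845 genes, where independent lists would share 74.8, and lower levels for 612, where they would share 58.1. Because bright genes were called more often under both conditions, lists independent at a given level would share more, which was not computed. Calls in opposite directions numbered 3 among genes higher and 1 among genes lower after withdrawal. Across all genes the 2 effects correlated at r = 0.680 (jackknife SE 0.0454), and at 0.995 (jackknife SE 0.133) with the noise variance removed. With the noise variance removed, the slope of the effect after withdrawal on that with GM-CSF was 1.10 (jackknife SE 0.217). No cells carried unmutated GNB1 in the vector, so effects of the mutant cannot be told apart from other differences between the lines. A lasting difference between the lines of any origin would also give this overlap.

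Bright genes were called more often. In the brightest of 4 equal bins of genes by mean level, withdrawal was called for 46.3% in empty vector and 41.5% in K89E cells, against 2.45% and 3.00% in the dimmest bin. The K89E effect was called for 24.8% of the brightest and 2.89% of the dimmest bin without GM-CSF, and for 20.6% and 0.764% with it.

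**Figure D3:**
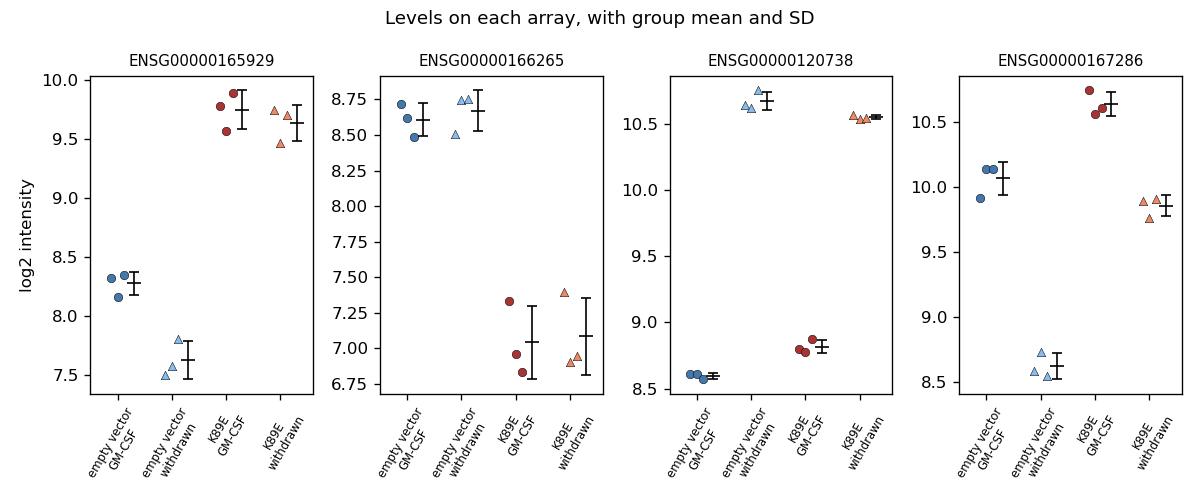
Log2 intensity (y axis) of the 4 named genes on each array, by group (x axis), with the group mean and SD (n = 3) beside the points. ENSG00000165929 and ENSG00000166265 part the lines under both conditions, ENSG00000120738 parts withdrawn from GM-CSF arrays, and ENSG00000167286 fell on withdrawal by 1.44 in empty vector and by 0.78 in K89E cells.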

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

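The tests of noise, of a single array, of scaling and of a compressed range behind the response slope, and of dim genes and of a single array behind the differing genes, were chosen after the result was seen. The withdrawal response differed between the lines for 15 genes by the test of the difference itself, among them ENSG00000167286 (log2 difference 0.66) and ENSG00000120738 (log2 difference -0.34), and this difference between groups is why they are listed here. The call of ENSG00000120738 was lost in 15 of its 21 alternatives and that of ENSG00000167286 in 10 of 21.

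Shuffling the residuals of a model without a difference argued against chance for these 15 genes: 1 of the 100 arrangements, the real one, called as many, and the highest of the others called 1. The top 15 genes of the 99 shuffles held a median of 7 with the smaller K89E response and 13 at most, and 0 of the shuffles had 15, which argues against selection of the top genes as the reason that all 15 changed less in K89E cells. Of the 15, 0 lay at or below the median level of all genes, which argues against dim probe sets. A single array as the source stays open. The most affected gene kept 85.6% of its difference with 1 array left out. Genes picked for a difference large against their spread could hardly lose most of it, so this cannot decide the question. The number of calls fell to 0 without K89E withdrawn replicate 1 or 3 or empty vector GM-CSF replicate 2 or 3. It was 1 without K89E GM-CSF replicate 2. These fits hold fewer arrays. Over all 12 fits without 1 array, the median difference stayed at 96.97% to 104.5% of its size. Genes picked in this way would keep their median as well, so it cannot decide the question either. A difference between the lines other than the mutant was not tested.

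The lower slope of the K89E response looked like a general weakening of the withdrawal response. Scaling between arrays stays open, though the slope was 0.863 after quantile normalization. The arrays had already been normalized, and their SDs of log2 levels differed by at most 1.02 times. A further normalization could hardly move the slope. A compressed range of the K89E arrays stays open, because normalization gave the arrays similar ranges and the lower level slope of 0.991 would follow either way. Noise in the empty vector response stays open, since the corrected slope of 0.887 lay within its jackknife SE of 0.124 from 1, and so does a single array, since the highest slope with 1 array left out was 0.969. Slopes as low arose in 15 of 100 arrangements of shuffled residuals, the real one included, with 0.746 the lowest of the others, so chance spread around equal responses may account for the lower slope.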

How the results depend on the processing

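The fit with 1 weight per group, the noise-corrected values, and the pseudocount and scaling of correlations and slopes were added after the data were seen. Counts of the 4 pairwise comparisons stayed within 1.5 times of the reported ones except as follows; where a change has no stated reason, the cause was not tested. Requiring a 2-fold change, which by construction removes small changes, left 39 and 23 genes for K89E without and with GM-CSF, 28 and 14 for withdrawal in empty vector and K89E cells, and 0 for the difference between responses. The fit on 2 groups called 1756 genes for K89E without GM-CSF, 742 of them lower, and array weights called 3226 for K89E with GM-CSF, 1624 of them lower, where a prior variance without a trend left 631 lower. The difference between responses was called for 5 genes with a prior variance without a trend. Leaving out 1 array gave 2027 to 2770 and 1307 to 2226 calls for K89E without and with GM-CSF, 3303 to 4662 and 2971 to 4132 for withdrawal in empty vector and K89E cells, and 0 to 13 for the difference.

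The arrays gave little sign that equal replicate numbers pair the samples. Deviations of same-numbered arrays correlated at -0.201 to 0.233, and those of differently numbered arrays at -0.210 to 0.200. In 16 of 36 comparisons an array's own number was the best match, where chance gives 12. A weak pairing is not excluded. With the replicate block the difference between responses was called for 8 genes, 0 of them negative, of which 7 were among the 15. The block moved no count of the 4 pairwise comparisons, in total or by direction, past 1.5 times.

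The correlation of withdrawal responses was 0.833 without the dimmest 33.3% of genes, 0.776 with a pseudocount of 16 and 0.678 to 0.723 with 1 array left out. That of K89E effects was 0.792, 0.728 and 0.633 to 0.679. The uncorrected slope over all genes, in place of those called in empty vector cells, was 0.673. Of 436 recomputed changes of the 4 named IDs over 5 comparisons, 402 kept direction and call. The call of the difference was lost for ENSG00000120738 in all 12 fits without 1 array and in 3 others, and for ENSG00000167286 in 10 settings, while without 1 array the differences stayed at -0.37 to -0.30 and 0.62 to 0.74. Of the changes of ENSG00000166265 that were not called, 2 turned sign with 1 array left out, ranging from -0.11 to 0.19 on withdrawal in K89E cells and from -0.18 to 0.12 for the difference. Not run were alternatives on probe sets of a gene, since each ID has 1 row, and those on GNB1 and gene lists.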

Other observations

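The averaged effects in this part were added after the first results had been seen. Both effects were averaged to ask whether K89E moves genes against the direction of withdrawal. The averaged effects draw on the same arrays with balanced signs, so equal noise adds no covariance. Their noise-corrected correlation across genes was -0.0116 (jackknife SE 0.0632), which argues against such an opposition over all genes. The uncorrected correlation was -0.0267, and unequal noise of the groups could account for 64.1% of that small covariance. Genes called for both effects numbered 464 higher in both, 590 higher in K89E cells and lower on withdrawal, 494 for the reverse and 853 lower in both. Independent lists would share 271, 336, 300 and 372, but bright genes are called more often for either effect, and independent lists within 20 equal bins of level would share 345, 533, 416 and 690. The remaining excess was not tested.

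The splits of samples into 3 and 3 number 10 and cannot give a share under 0.1, and in each pairwise comparison 1 split, the real one, gave as many calls. The real and highest other counts were 2756 and 0 for K89E without GM-CSF, 2113 and 1 for K89E with it, 4492 and 0 for withdrawal in empty vector cells, and 3937 and 2 for withdrawal in K89E cells. For the averaged effects, 1 of 100 splits within conditions or lines, the real one, gave as many calls. The real counts were 4361 genes for K89E, with 48 the highest other, and 6450 for withdrawal, with 1138 the highest other. This argues against chance spread between arrays, though 1 of 100 is the lowest share such splits can give. The splits cannot tell the mutant from another difference between the lines, or either effect from a batch that follows the groups.

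The root mean variance of log2 levels within a group was 0.117 in empty vector and 0.110 in K89E cells after withdrawal, against 0.0823 and 0.0978 with GM-CSF; the differences were not tested. The spread of single pairs of arrays ran from 0.107 to 0.131 after withdrawal and from 0.0800 to 0.0839 with GM-CSF in empty vector cells, and from 0.103 to 0.116 and from 0.0892 to 0.106 in K89E cells. By level, the corrected slope of the K89E on the empty vector withdrawal response was 0.842, 1.10, 0.854 and 0.841 from the dimmest to the brightest of 4 equal bins of genes.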
